A study of Homo sapiens with 15 samples.

How the data were processed

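Chromatin accessibility was measured by Omni-ATAC-seq, in which a transposase inserts sequencing adapters into open DNA of permeabilised nuclei, with Nextera chemistry and paired-end sequencing per the labels. The cells were OCI-Ly7 and SU-DHL-4, established lines of diffuse large B cell lymphoma of germinal centre type. Per the labels, both lines carried dCas9 fused to the KRAB repressor domain and received lentiviral guides against POU2F2, against POU2AF1, or non-targeting guides as the control.

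Per the submitters' processing notes, reads were aligned with Bowtie2 to build GRCh38 and Genrich was used, without versions or settings. The deposited lists hold peak intervals in base pairs called separately for each library, with 3 scores for each summit; the lists name no caller. From the values, the deposited scores behave as a fold enrichment, a −log10 p and a −log10 q, and the smallest −log10 p was 3.00 in these libraries. All scores are the authors' own and were used only to describe, rank or filter peaks within a list. Of the 15 libraries in the series, 13 had a peak list, and the 2 SU-DHL-4 POU2AF1 knockdown libraries were not analysed here. Read depth is unknown, so the number of peaks is the only trace of it. The lists cover chromosomes 1 to 22.

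A peak was taken as an interval with its best summit. Peaks were ranked within each library by the second score, and the rank is given as a percentile, so that strong peaks have low ranks. Lists were shortened to the shortest list of the line, 58900 peaks in OCI-Ly7 and 84374 in SU-DHL-4. Regions of 501 bp were centred on summits, best rank first, and overlapping ones were dropped. A library had a region when a listed peak overlapped its central 201 bp by at least 1 bp. A lost region was present in every control library and in no knockdown library, and a gained region was the reverse. Positions are on GRCh38, counted from 1.

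Each region was assigned to the nearest gene within 100 kb. The gene table (GRCh38.p14, 18421 genes) gives no strand, so distances run to the annotated span, and a region at a gene end lies within 1 kb of either end of a gene. The design had named transcription start sites and chromosome X, which the table and the lists did not give. No genome sequence was at hand, so the planned counts of the octamer motif were not run.

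Counts of lost and gained regions were compared with the same counts in every other split of the same libraries into groups of the same sizes. Means of libraries were compared by two-sided exact permutation tests of the difference, and the smallest p that the group sizes allow is given. Shares at gene ends were compared between lost or gained regions and other regions by two-sided Cochran-Mantel-Haenszel tests within 10 strata of rank, with 95% confidence intervals. Those tests, and the tests of overlap between lines, take regions as units. Members of 14 fixed gene lists were counted among genes with a lost or gained region. They were compared with 10000 random gene sets (two-sided permutation p). The sets were matched on the number of regions that could have been lost or gained, and not on rank. P-values were adjusted by the Benjamini-Hochberg method within each family, which held 84 list tests, 12 tests of library means and 6 tests of gene ends. The threshold was an adjusted p of 0.05. Of the 355 list symbols, 348 were in the gene table.

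The comparisons, gene lists, named-gene rule and most alternatives were fixed before the data were examined. The rule named the targeted genes, the 10 best ranked lost and gained regions of each comparison, up to 4 members of each list, and the BCL6, CIITA, MEF2B, S1PR2, PRDM1 and IRF4 loci. The best ranked regions without a peak within 1 kb in the other group were added later, because wide peaks called as different intervals can leave a region between them. The alternatives were the deposited list lengths, the strongest 50% of each list, ranking by the first score, a −log10 q of at least 5, wider overlap, a margin rule, same-numbered libraries, library series, assignment within 25 kb and leaving out each library. The labels number the libraries, and the series 1 to 10 and 37 to 51 were treated as possible batches.

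The counting was tested on simulated data made from the lists. Of the regions removed from the knockdown lists of the comparisons, 81, 79 and 96 were in every simulated control list. All of these were recovered, and removed regions not in every control could not be. The definition of a lost region requires this, so it checks only the code. In OCI-Ly7 the simulated noise did not include differences between library series. Every simulated library was a copy of 1 control list with noise in the scores only. Differences in which peaks were called, and in their edges, were thus absent. Score noise alone gave another 381, 82 and 392 lost regions that had not been removed or lowered. These counts do not measure the spread between real libraries. In SU-DHL-4 the real splits that mixed control and knockdown libraries lost 1600 and 1763 regions. Regions lowered 4-fold in score were recovered as lost in 36.8%, 36.4% and 31.9% of cases, among those in every simulated control. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.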

Results

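Open chromatin was profiled in a pair of germinal centre lymphoma lines after silencing of POU2F2 or POU2AF1. POU2F2 encodes OCT2, a transcription factor that binds the octamer motif, and POU2AF1 encodes OCA-B, a B cell coactivator that binds OCT factors on DNA. OCI-Ly7 had 3 control, 2 POU2F2 knockdown and 4 POU2AF1 knockdown libraries, and SU-DHL-4 had 2 control and 2 POU2F2 knockdown libraries. The lists held 65893 ± 9075 peaks in OCI-Ly7 controls (SD, n = 3), 64560 ± 749 after POU2F2 knockdown (SD, n = 2) and 72599 ± 2760.1 after POU2AF1 knockdown (SD, n = 4). In SU-DHL-4 they held 87046 ± 3779 peaks in controls (SD, n = 2) and 95411 ± 4132 after POU2F2 knockdown (SD, n = 2). Tests of the number of peaks gave a two-sided exact p of 1 for POU2F2 and 0.286 for POU2AF1 knockdown in OCI-Ly7. In SU-DHL-4 both knockdown lists were longer than both control lists, and 2 libraries against 2 cannot give an exact p under 0.333. The labels do not say that replicates were separate cultures, so exact p-values measure only the spread between these libraries. P-values of the gene-end, gene-list and overlap tests take regions or genes as units and do not measure that spread. In OCI-Ly7, peaks lay at the ends of 84.8% of germinal centre genes in controls, 84.8% after POU2F2 and 81.8% after POU2AF1 knockdown. The shares of immunoglobulin genes were 33.3%, 20.6% and 32.4% in that order, and those of T cell markers 55.0%, 47.5% and 46.3%. In SU-DHL-4 the share of immunoglobulin genes was 26.5% in controls and 41.2% after POU2F2 knockdown, and these shares were not tested.

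The comparison of POU2AF1 knockdown with control in OCI-Ly7 asked where open chromatin depends on OCA-B. The peak at the POU2AF1 promoter (gene 5450, chromosome 11, 111379143 to 111379643) ranked at percentile 5.71 ± 1.06 in controls (SD, n = 3) and at 13.4 ± 3.64 after POU2AF1 knockdown (SD, n = 4). It ranked lower in all 4 knockdown libraries than in any control library, with an exact p of 0.0571, the smallest possible. Within the library series 1 to 10, the weakest control rank of the POU2AF1 promoter was 5.49 and the best knockdown rank was 12.6. In the other series the ranks were 6.87 in the control library and 8.68 in the knockdown library. The groups overlapped at the POU2AF1 promoter in the deposited lists (exact p 0.114) and when peaks were ranked by the first score (exact p 0.171), settings added later. After POU2F2 knockdown the POU2AF1 promoter ranked at 6.08 (n = 2, exact p 1 against control).

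Upstream of BCL6, which encodes the repressor that maintains the germinal centre state, 0 of the 23 regions present in every OCI-Ly7 control were lost after either knockdown, and 22 were present in every library after each. The region about 156 kb upstream of BCL6 (chromosome 3, 187900803 to 187901303) was singled out after its values were seen. It ranked at 15.1 ± 2.60 in OCI-Ly7 controls (SD, n = 3) and at 59.0 ± 18.6 after POU2AF1 knockdown (SD, n = 4, exact p 0.0571, the smallest possible). The POU2AF1 knockdown ranks of this BCL6 region ran from 42.8 to 85.8, and the control ranks from 12.7 to 17.9, so the groups did not overlap in either library series. After POU2F2 knockdown in OCI-Ly7 the BCL6 region ranked at 26.3 ± 6.93 (SD, n = 2, exact p 0.2, the smallest possible). In SU-DHL-4 it ranked at 4.27 ± 0.0964 in controls (SD, n = 2) and 13.6 ± 1.41 after POU2F2 knockdown (SD, n = 2, exact p 0.333, the smallest possible). Among 7855 OCI-Ly7 regions with similar control ranks, 11 dropped as far as this BCL6 region on POU2AF1 knockdown and 342 as far as it did on POU2F2 knockdown, and in SU-DHL-4 the count was 93 of 3138. The control interval at this BCL6 region was 919 to 1173 bp wide in OCI-Ly7, against 185 to 471 bp after POU2AF1 knockdown and 474 to 478 bp after POU2F2 knockdown. The adjoining BCL6 region (187901326 to 187901826), under the same control interval, ranked at 66.3 ± 27.3 after POU2F2 knockdown (SD, n = 2), where 46 of 7855 similar regions dropped as far. After POU2AF1 knockdown it was in 3 of 4 lists, at 66.2 to 87.5. A further BCL6 upstream region (187902042 to 187902542) ranked at 18.4 ± 3.64 in OCI-Ly7 controls (SD, n = 3), at 24.8 ± 1.97 after POU2AF1 knockdown (SD, n = 4) and at 16.2 ± 1.20 after POU2F2 knockdown (SD, n = 2). In SU-DHL-4 the neighbour of the BCL6 region (187902012 to 187902512) ranked at 5.74 ± 0.339 in controls and 17.7 ± 3.66 after POU2F2 knockdown (SD, n = 2 each), a drop no smaller than that of the region singled out.

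**Figure D1:**
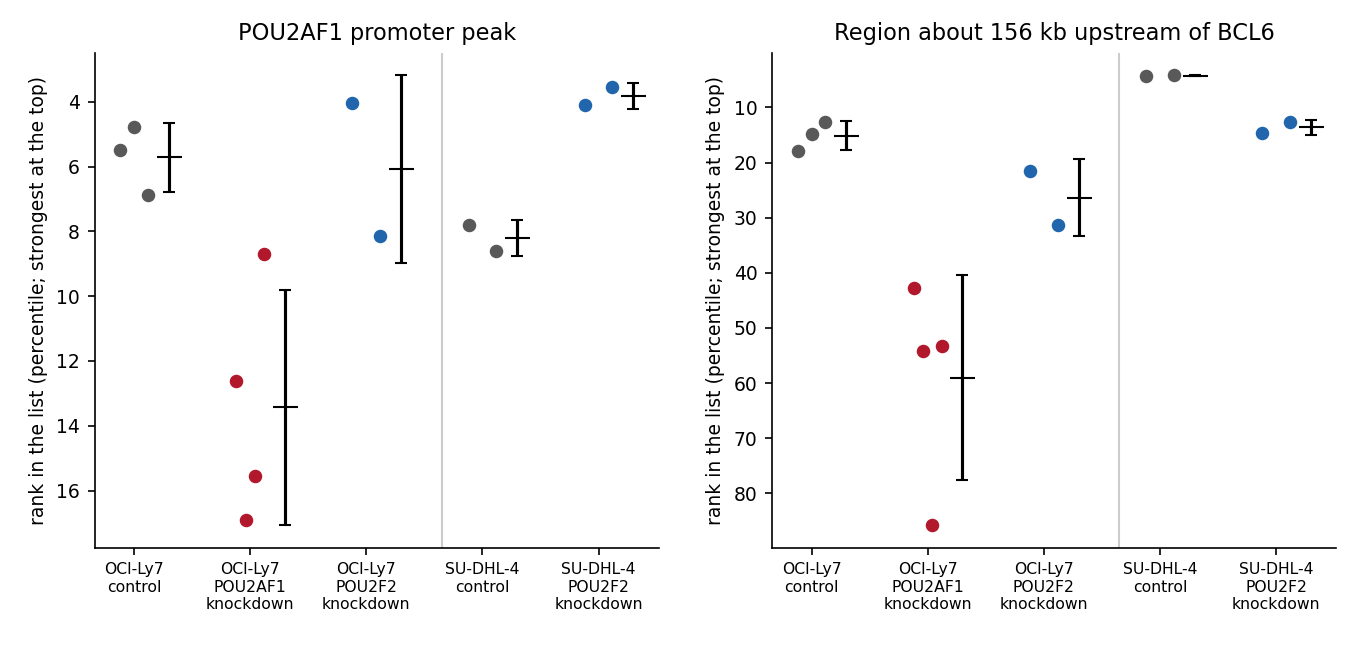
Percentile rank, strongest at the top, of the POU2AF1 promoter peak and of the region about 156 kb upstream of BCL6, with a point per library and the mean ± SD beside each group. The 4 POU2AF1 knockdown libraries stand between 42.8 and 85.8 at the BCL6 region, and the OCI-Ly7 controls between 12.7 and 17.9.

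Regions lost on POU2AF1 knockdown in OCI-Ly7 included one inside EEIG1 (chromosome 9, 127979233 to 127979733, control rank 45.3 ± 11.1, SD, n = 3). Regions inside KAZN (58.8 ± 7.99), near MMD (59.6 ± 7.71), inside CUX1 (60.8 ± 19.3) and inside the ubiquitin ligase gene CBL (61.5 ± 21.3) were lost without a knockdown peak within 1 kb. So were regions inside SPOCK1 (62.8 ± 5.23) and inside PRELID2 (63.7 ± 19.4). PLXNC1, TMX3, SLC23A2, ARL6IP5 and ARHGAP5 had lost regions too, each beside a knockdown peak within 1 kb in all 4 libraries. Among germinal centre genes, 2 of 32 had a lost region, KLHL6 (62.5 ± 38.6) and IRAG2 (80.6 ± 15.7). Among immunoglobulin constant region genes, 2 of 10 did, IGHA1 (91.7 ± 6.14) and IGHA2 (82.4 ± 16.8), against 0.354 by chance (permutation p 0.0836). EPCAM was the member among the non-haematopoietic markers, and the other lists had 0 members with a lost region.

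Gained regions on POU2AF1 knockdown lay inside KLF10 (chromosome 8, 102651731 to 102652231, knockdown rank 48.2 ± 5.56, SD, n = 4), near the ETS family gene ELK3 (49.9 ± 9.78), inside RAB30 (54.1 ± 7.91) and inside TTLL7 (60.2 ± 8.04). KLF12 (16.7 ± 3.88) and EBF1 (51.6 ± 21.5) gained regions beside a control peak within 1 kb in all 3 controls. PTPN2 (55.1 ± 5.65), NCOA3 (58.1 ± 4.82) and FOXO3 (59.8 ± 14.3) gained regions beside a control peak in 1 or 2 controls. Among myeloid markers, CSF1R (86.6 ± 10.8) and MRC1 (80.7 ± 8.93) had weak gained regions, 2 of 15 members against 0.125 by chance (permutation p 0.0128, adjusted p 1). FLI1, CAV1, HLA-DQA1, ITGB1, OAS3 and PECAM1 were the other list members with a gained region. In all, 125 regions were lost, 0.303% of those in every control, and 200 were gained. Of the 35 splits of these libraries, 22 gave as many lost and 8 as many gained regions, the real one included. The share of lost regions at gene ends did not pass the test against regions of their rank (odds ratio 1.38, 95% interval 0.783 to 2.42, adjusted p 0.317), and gained regions lay there less often (odds ratio 0.453, 0.222 to 0.924, adjusted p 0.0375).

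The comparison of POU2F2 knockdown with control in OCI-Ly7 asked the same of OCT2. At POU2F2 itself (gene 5452, chromosome 19, 42086110 to 42197936), the peak beyond the upper end of the gene (42199002 to 42199502) ranked at 25.1 ± 4.92 in controls (SD, n = 3) and 26.2 ± 1.77 after POU2F2 knockdown (SD, n = 2), a difference within the spread. Inside the gene, the groups also overlapped at strong regions at 42113937 (3.65 ± 4.30 and 5.43 ± 0.689) and 42129517 (12.8 ± 5.16 and 7.47 ± 0.630). Weaker POU2F2 regions at 42087398 and 42182183 were in 2 of 3 controls and in neither POU2F2 knockdown library. After POU2AF1 knockdown the region at 42182183 was in 0 of 4 libraries too, and that at 42087398 in 2 of 4. The absence at 42182183 was thus not particular to POU2F2 knockdown. Regions at 42121746 and 42185182, in 2 of 3 controls too, ranked better in both POU2F2 knockdown libraries. The strongest isolated loss was inside RCSD1 (chromosome 1, 167669319 to 167669819, control rank 36.98 ± 4.86, SD, n = 3), a region that was also absent from 3 of the 4 POU2AF1 knockdown libraries. C14orf132 (40.7 ± 7.67), MIGA1 (42.7 ± 8.26), MATCAP1 (46.4 ± 9.91), NDUFV2 (46.4 ± 3.74), LRRK2 (47.1 ± 5.25), LDAH (47.6 ± 11.6), MCM9 (47.95 ± 7.69) and MED15 (48.3 ± 32.9) followed, none with a knockdown peak within 1 kb. Among the best ranked of all lost regions were those at CNPY2 (0.919 ± 1.21), CDC73 (2.58 ± 1.42), LSS (3.08 ± 0.175), CEP43, BRCA2, KMT2C, IPO7, PRR3 and RFX3, and each of these had a peak within 1 kb in both knockdown libraries.

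B cell identity and receptor signalling genes had lost regions at 9 of 39 members on POU2F2 knockdown in OCI-Ly7, against 5.90 by chance (permutation p 0.222). They included the kinase gene PRKCB (51.9 ± 8.26, SD, n = 3), the lymphoid factor IKZF1 (61.9 ± 9.45) and the inhibitory receptor CD22 (62.8 ± 2.52), with ranks in controls, and ETS1, FCRL3, LYN, SYK and TCF4. Germinal centre genes had 5 of 32, BACH2, IRAG2, LMO2, MYBL1 and SUGCT, against 4.94. Plasma cell genes had 3 of 24, SLAMF7, ZBTB20 and PRDM1, whose region lay 81522 bp from the gene (74.9 ± 7.86). Dark zone genes had 3 of 28, CXCR4, MKI67 (67.6 ± 15.9) and RRM2, and apoptosis genes 3 of 14, BCL2L1, BIK and BOK. Immunoglobulin genes had 3 of 10, IGKC, IGLL5 and IGHA2, memory B cell genes 2 of 26, CD44 and RUNX3, and NF-kB genes 1 of 28, BCL2A1 (70.6 ± 9.16). EPCAM and PECAM1 were the non-haematopoietic members, and MHC class II, interferon, T cell and housekeeping genes had 0.

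Gained regions on POU2F2 knockdown in OCI-Ly7 lay inside PARVB (chromosome 22, 44042253 to 44042753, knockdown rank 43.7 ± 1.54, SD, n = 2), TBCD (47.8 ± 9.57), KLF10 (49.6 ± 1.80), MCF2L (50.6 ± 10.4), BMPR1B (51.7 ± 12.5), RAB30 (52.1 ± 8.74) and RHOBTB1 (53.6 ± 2.72), none with a control peak within 1 kb. INTS6, SEMA4B, PAG1, NCOA2, USP38 and MEIS2 gained regions beside peaks of all 3 controls. Plasma cell genes had gained regions at 4 of 25 members, CAV1, TNFRSF17, FNDC3B and JCHAIN, against 2.15 by chance (permutation p 0.317). B cell identity genes had 4 of 39, ETS1, FLI1, LYN and SYK, against 6.22, and germinal centre genes 5 of 32, among them FAS (67.0 ± 7.75) and BCL11A. ZEB2 (54.9 ± 5.76), FCRL2, SAMSN1 and ITGA4 were the memory B cell members. In all, 949 regions were lost, 2.30% of those in every control, and 907 were gained. Lost regions lay at gene ends in 15.9% of cases, against 28.3% of all regions in every control, but more often than regions of their own rank (odds ratio 1.89, 95% interval 1.55 to 2.29, adjusted p 4.36e-10), and gained regions less often (6.62%, odds ratio 0.656, 0.5004 to 0.860, adjusted p 0.00627). The gene-end tests took regions as units, so their p-values do not measure the spread between libraries. Gene ends were not tested in the other splits. Of the 10 splits of these libraries, 2 gave as many lost and 4 as many gained regions, the real one included, and the split that followed the library series gave 1156 and 2014.

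The comparison of POU2F2 knockdown with control in SU-DHL-4 asked the OCT2 question in the other line. The strongest isolated loss lay 26480 bp from FOXO1 (chromosome 13, 40692871 to 40693371, control rank 28.2 ± 3.96, SD, n = 2), the gene of a transcription factor of the germinal centre dark zone. HELZ (chromosome 17, 67132332 to 67132832, 29.1 ± 3.04), the Hippo kinase gene STK4 (38.05 ± 5.49), EXOC3L4 (38.5 ± 4.58), TCP11L2 (40.1 ± 7.71), LDAH (40.3 ± 4.85), RNF112 (41.1 ± 1.14) and GNA12 (41.2 ± 5.44) lost regions without a knockdown peak within 1 kb. At POU2F2 itself the peak beyond the upper end (42198909 to 42199409) ranked at 34.7 ± 3.59 in controls and 28.4 ± 5.77 after knockdown, and the next one outward (42199432 to 42199932) at 34.2 ± 4.22 and 44.8 ± 11.997 (SD, n = 2 each). Weaker POU2F2 regions at 42179187 and 42084519 were in both controls and in neither knockdown library. Those at 42184274 (48.2 ± 9.69 in controls, 77.9 ± 9.46 after knockdown) and 42133097 (40.8 ± 5.16 and 55.6 ± 10.2) ranked lower in both knockdown libraries. POU2F2 regions at 42201448 (85.2 ± 1.78 in controls, 47.7 ± 3.58 after knockdown), 42121764 (74.4 ± 6.41 and 42.4 ± 0.713) and 42092324 (67.6 ± 0.484 and 44.8 ± 3.59) ranked better in both knockdown libraries (SD, n = 2 each). In OCI-Ly7 the region matching 42184274 (start 42184281) ranked at 49.5 ± 7.31 in controls (SD, n = 3). It ranked at 70.9 ± 6.81 after POU2AF1 knockdown (SD, n = 4), where POU2F2 was not targeted. After POU2F2 knockdown in OCI-Ly7 it ranked at 56.3 ± 17.7 (SD, n = 2), which overlapped the controls. In SU-DHL-4 the POU2AF1 promoter peak ranked at 8.20 ± 0.546 in controls and 3.82 ± 0.406 after POU2F2 knockdown (SD, n = 2 each).

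Germinal centre genes had lost regions at 14 of 33 members on POU2F2 knockdown in SU-DHL-4, against 12.1 by chance. They included GNA13 (62.3 ± 10.4, SD, n = 2) and SWAP70 (64.6 ± 2.89), with ranks in controls, neither beside a knockdown peak, and BACH2, BCL11A, BCL6, BMP7, EZH2, IRF8, KLHL6, LMO2, MME, MYBL1 and SUGCT. B cell identity genes had 15 of 39 against 13.6, among them ETS1, RASGRP3, CD72 and PTPN6, and plasma cell genes 6 of 24 against 4.64, among them TXNDC5 and CD38. KLF2 (60.6 ± 4.92) was among 7 memory B cell members, and IGKC (58.9 ± 4.97) and VPREB1 among 4 of 13 immunoglobulin genes. BCL2 (45.7 ± 13.0) was the apoptosis gene with a lost region, beside peaks of both knockdown libraries, and CIITA (69.3 ± 3.11) and CD86 were the MHC class II genes. Dark zone genes had 4 of 27, BUB1B, CCND3, CXCR4 and FOXO1, and NF-kB genes 3 of 29, BCL2A1, REL and BIRC3. T cell, myeloid and non-haematopoietic markers had 3 members each, interferon genes 1, IFITM3, and housekeeping genes 4 of 18 against 3.77.

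Gained regions on POU2F2 knockdown in SU-DHL-4 lay near the cyclin gene CCNG2 (chromosome 4, 77153003 to 77153503, knockdown rank 36.2 ± 1.17, SD, n = 2), and at GGA3 (36.9 ± 0.914), PLEKHH2 (37.8 ± 2.22), LRRK2 (37.9 ± 4.46), ZNF250 (38.1 ± 8.38) and DPF3 (38.4 ± 7.12), none with a control peak within 1 kb. NF-kB genes had gained regions at 6 members against 5.98 by chance, TRAF1 (47.2 ± 0.888), NFKB1 (66.0 ± 4.08), MYC (67.0 ± 6.51), BATF, EBI3 and EGR1. Plasma cell genes had 7 of 25 against 5.06 (permutation p 0.453), ERN1 (61.4 ± 3.97), GLDC (61.1 ± 3.92), EDEM1, IRF4, SDC1, SEL1L and ZBTB20. RGS13 (44.3 ± 12.2) led 9 germinal centre members, CCND2 (56.8 ± 2.92) 4 dark zone members with MKI67, CXCR4 and FOXO1, and BLK 12 B cell identity members. In all, 3012 regions were lost, 4.45% of those in every control, and 3207 were gained, and the other 2 splits of these libraries gave at most 1763 and 1461, too few splits to judge against chance. In the deposited lists another split lost more regions (2519) than the knockdown (2340). The share of lost regions at gene ends did not pass the test (odds ratio 0.988, 95% interval 0.850 to 1.15, adjusted p 0.880), and gained regions lay there less often (0.827, 0.711 to 0.963, adjusted p 0.0274). Of the 84 tests of gene lists in the comparisons, 0 passed, and every adjusted p was 1.

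**Figure D2:**
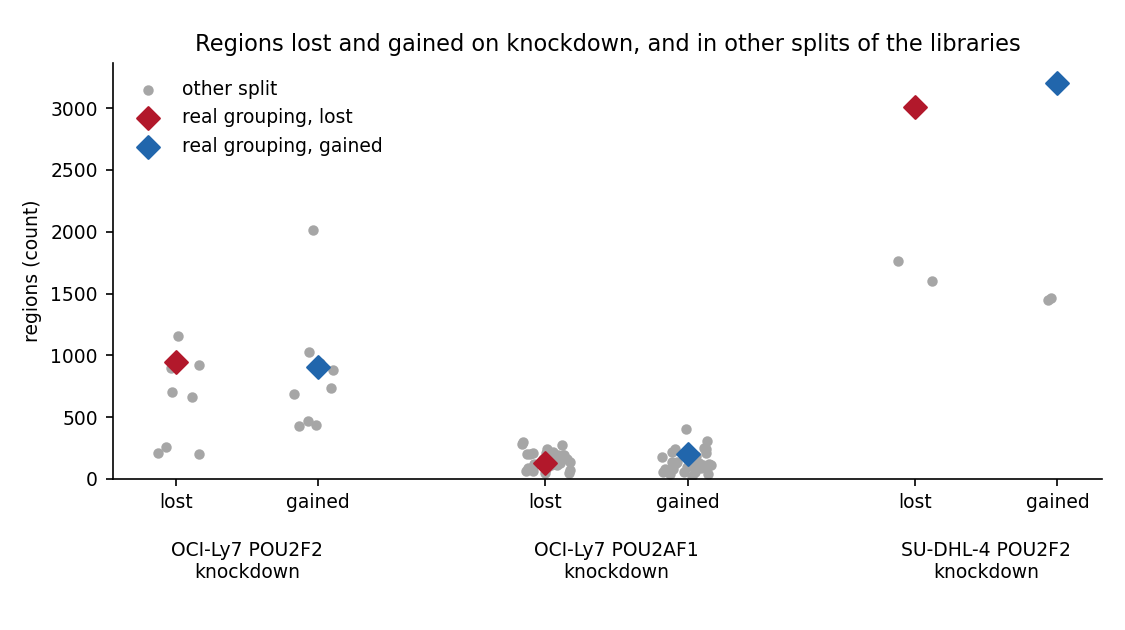
Number of regions lost and gained in each comparison (coloured diamonds) and in the other splits of the same libraries into groups of the same sizes (grey points). In SU-DHL-4 the knockdown gave 3012 and 3207 regions against at most 1763 and 1461 in only 2 other splits, and on POU2AF1 knockdown the counts of 125 and 200 lay among those of other splits.

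At the other fixed loci, CIITA kept 10 of 12 control regions in OCI-Ly7 on POU2F2 knockdown and lost 1, and kept 17 of 22 in SU-DHL-4 and lost 4. In SU-DHL-4, 2 of 33 BCL6 upstream regions were lost and 1 was gained, and S1PR2, the gene of a receptor that holds B cells in the germinal centre, lost 1 of 18. MEF2B lost 1 of 12 in OCI-Ly7 on POU2F2 knockdown. The PRDM1 locus lost 0 in each comparison, and IRF4 lost 0 and gained 1 in SU-DHL-4.

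IRAG2, EPCAM and IGHA2 had lost regions after both knockdowns in OCI-Ly7, and LDAH had them on POU2F2 knockdown in both lines. IRAG2 also had a gained region in SU-DHL-4, and EPCAM had one on POU2F2 knockdown in OCI-Ly7. Other list genes had lost regions on POU2F2 knockdown in both lines too, among them BACH2, LMO2 and MYBL1. In OCI-Ly7 both knockdowns lost 63 regions in common, against 2.88 if independent. Of the 907 and 200 gained regions, 59 were gained after both, KLF10 and RAB30 among them, and no expected value was computed for that overlap. Because both were set against the same controls, 1000 simulations with shared controls were run, which gave 13.0 on average and 26 at most with 637 and 74.4 lost regions. Scaled to the measured 949 and 125 lost regions, they gave 32.6 on average and 52 at most. The overlap of 63 was not tested within a library series, so a part of series in it cannot be told apart from shared loss. Set directly against each other in OCI-Ly7, 467 regions were present only after POU2F2 knockdown and 1006 only after POU2AF1 knockdown, and the other splits of those libraries gave at most 778 and 475. Both POU2F2 knockdown libraries came from the later library series and 3 of the 4 POU2AF1 knockdown libraries from the earlier one, so the series and the gene cannot be told apart there. Between lines, 29 regions led by LDAH, LHFPL2, TPRA1 and RFC3 were lost on POU2F2 knockdown in both (odds ratio 1.62, 95% interval 1.08 to 2.43, two-sided p 0.0178). LDAH was among the 13 of these 29 without a knockdown peak within 1 kb, and LHFPL2, TPRA1 and RFC3 were not. In both lines 28 regions were gained (odds ratio 1.78, 95% interval 1.19 to 2.69, p 0.00521).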

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

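The tests by splits of the libraries, and by library series for the POU2F2 counts and the POU2AF1 promoter, were chosen after the results were seen. Among the 4 POU2AF1 knockdown libraries, the only group of at least 4, no library was flagged as standing apart in 8 measures. Replicate 4, from the later library series, still differed from the others. Its share of regions in common with replicates 1, 2 and 3, out of those in either library, was 0.723 to 0.738. Among replicates 1, 2 and 3 that share was 0.758 to 0.772. The effect of POU2F2 knockdown was not shown to differ between the lines in peak number (exact p 0.267) or in the share of peaks at gene ends (exact p 0.317).

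POU2F2 knockdown in OCI-Ly7 lost 949 and gained 907 regions, RCSD1 and PRKCB among the lost and KLF10 among the gained. Exchanging control replicate 3, the only control of the later library series, with a knockdown library left 0.973 of the lost count at the lowest, so library series is a candidate explanation for the number lost. For gained regions that ratio was 0.755, which leaves series and knockdown unseparated because only 1 control library shares the series of the knockdown. Of the 949 lost regions, 29.1% had a knockdown peak within 1 kb, and in SU-DHL-4 25.9% of the lost regions did. Edges of wide peaks may thus account for a part of the counts and cannot be told apart from small shifts of the open site. Whether the regions with such a peak are also those that follow the series was not tested. An effect of OCT2 stays open, and no share of the regions can be assigned to it.

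The POU2AF1 promoter ranked lower after POU2AF1 knockdown. Library series is argued against, since within the series 1 to 10 the best knockdown rank lay 7.13 percentile points beyond the weakest control rank. A general drop of strong peaks is argued against by the 1.40% of regions of similar control rank that dropped as far. Repression of its own promoter by dCas9-KRAB stays as a hypothesis, with an exact p of 0.0571 that 3 against 4 libraries cannot better, and of 0.114 and 0.171 in the deposited lists and by the first score. In SU-DHL-4 the POU2AF1 promoter ranked better after POU2F2 knockdown (3.82 ± 0.406) than in controls (8.20 ± 0.546, SD, n = 2 each), without overlap. A shift in rank at this promoter, there in the other direction, thus occurred without guides against it.

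On POU2AF1 knockdown the counts of 125 lost and 200 gained regions were matched by chance splits, since 22 of 35 and 8 of 35 splits gave as many (at most 296 and 403). These splits exchange libraries between the library series, so a difference between series can raise their counts. Within the strongest 50% of the lists, 137 regions left, among them regions of EBF1, SYK, ETS1 and BCL11A, and 1 of 35 splits, the real one, gave as many (highest other 118), 1 of the 7 settings compared. Within the series 1 to 10 the count was 471 and no other split gave as many (at most 352), which goes against series alone. With 10 splits the real one ranks first by chance 1 time in 10, so this evidence is weak. Of the 137 regions, 40.1% lay outside the strongest 50% of both POU2F2 knockdown lists, no more than in other splits (21 of 35 gave as high a share). Loss of OCA-B may weaken these regions, as a hypothesis.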

How the results depend on the processing

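The tests without a peak within 1 kb, with summits in the region, at the POU2AF1 promoter and at BCL6 under other settings, and of the gene lists in the strongest 50%, were chosen after the results were seen.

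Of the results under alternatives, 81 stayed alike (a count within 1.5 times, a value within the spread between libraries, or a test on the same side of its threshold), 59 moved and 1 reversed. The POU2AF1 promoter kept its direction, with 5.67 percentile points in the deposited lists, 10.1 when ranked by the first score and 6.57 to 9.31 leaving out each library, but the groups no longer separated in the deposited lists (exact p 0.114) and by the first score (exact p 0.171). The BCL6 region kept its direction too, at 34.2 to 49.2 points over these settings on POU2AF1 knockdown, 6.29 to 16.1 on POU2F2 knockdown in OCI-Ly7 (exact p 0.4 by the first score) and 7.95 to 10.4 in SU-DHL-4. No gene list passed over the 84 tests under any of the alternatives run. The shared losses between lines kept an odds ratio of 1.65 in the deposited lists, and the margin rule left 0 of them among 24 and 11 regions. In the deposited lists another split of the SU-DHL-4 libraries lost more regions (2519) than the real one (2340).

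The counts of regions moved, and the cause was not tested except where fewer libraries or shorter lists require it. In the strongest 50% of the lists POU2F2 knockdown gave 483 lost and 402 gained in OCI-Ly7 and 1613 and 1456 in SU-DHL-4, and POU2AF1 knockdown 75 gained. The margin rule (present in the strongest 50%, absent from the whole list) left 24 and 5, 0 and 1 for POU2AF1, and 27 and 39 in SU-DHL-4, and 0 shared losses between the OCI-Ly7 knockdowns. The stricter score left 572 gained on POU2F2 knockdown and 43 lost on POU2AF1 knockdown, and coverage of 50% of the region 371 gained on POU2F2 knockdown in OCI-Ly7 and 1856 lost in SU-DHL-4. Deposited list lengths gave 76 and 320 for POU2AF1, and 81 lost regions had no peak within 1 kb. The share of peaks at gene ends in SU-DHL-4 reversed from 0.0705 to −0.822 percentage points in the deposited lists, the cause was not tested, and neither passed a test.

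Only the series 37 to 51 gave 7700 and 3703 regions for POU2F2 and 9672 and 11519 for POU2AF1 in OCI-Ly7, with 1 control library. Only the series 1 to 10 gave 731 and 737 for POU2AF1. Treating same-numbered replicates as a block gave 2963 and 2063 for POU2F2 and 211 and 404 for POU2AF1 in OCI-Ly7, and 3012 and 3207, as before, in SU-DHL-4. The OCI-Ly7 counts equal those without the unmatched library, control replicate 3 for POU2F2 and POU2AF1 knockdown replicate 4 for POU2AF1. With group mean ranks per region removed, same-numbered libraries correlated at 0.0684, 0.0740 and −0.168 for POU2AF1, so pairing was not shown. For POU2F2 the removal forces mirrored values, which cannot tell. Control replicate 3 and POU2AF1 knockdown replicate 4 (later series) correlated at 0.338. Pairs across series were at −0.222 to −0.115, lowered by the removal.

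Leaving out each library asks fewer libraries to hold a region and gave 1378 to 2963 lost and 1168 to 5343 gained for POU2F2 in OCI-Ly7, 205 to 529 and 357 to 995 for POU2AF1, and 5681 to 8750 and 5452 to 8988 in SU-DHL-4. Every library moved some count by over 1.5 times: without POU2F2 knockdown replicate 1 or 2 in OCI-Ly7, 5343 and 5120 were gained, and without control replicates 1, 2 and 3, 450, 355 and 529 were lost for POU2AF1. Without POU2AF1 knockdown replicates 1, 2, 3 and 4 the lost count was 205, 231, 232 and 211. Without SU-DHL-4 control replicates 1 and 2 it was 8750 and 8240, and without the knockdown replicates 5681 and 5948. The octamer alternatives were not run for want of a genome sequence. Read depth is unknown, so weak regions absent from a list are not shown to be closed.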

Other observations

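The tests by gene list in the strongest 50% of the lists were chosen after the counts there had been seen, and the tests of region sets between lines were written before their results were seen, except that leaving out libraries there was chosen after.

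Regions of B cell receptor and identity genes were among those that left the strongest 50% of the lists on POU2AF1 knockdown in OCI-Ly7. The list had 6 of 39 members there, EBF1, ETS1, LYN, PTPN6, SYK and VPREB3, against 1.30 by chance (permutation p 0.0016, adjusted p 0.0224 over the 14 lists), and it did not pass over all 84 tests (adjusted p 0.134). In the whole lists 0 of the 39 members had a lost region, and EBF1 and FLI1 had gained ones. The EBF1 region (chromosome 5, 159094728 to 159095228) ranked at 36.2 ± 1.39 in controls (SD, n = 3) and at best at 50.7 after knockdown, the SYK region (chromosome 9, 90813364 to 90813864) at 40.2 ± 5.88 and at best at 69.0, and the ETS1 region at 45.3 ± 0.792 and at best at 61.0. The best knockdown ranks of EBF1, LYN (50.9), PTPN6 (51.8) and VPREB3 (55.7) lay closer to the limit of 50% than those of SYK and ETS1. The BCL11A region ranked at 41.6 ± 1.70 in controls and at best at 70.5, and FCRL4 (34.5 ± 6.34), IRF8 (42.7 ± 4.90) and RCSD1 (36.98 ± 4.86) were among the others. Of these 137 regions, 93 (67.9%) were still in the whole list of every knockdown library and 0 were absent from all.

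A FOXO1 region left the strongest 50% of the lists in both lines on POU2F2 knockdown, at different sites. In OCI-Ly7 the region inside FOXO1 (chromosome 13, 40664560 to 40665060) ranked at 32.7 ± 14.3 in controls (SD, n = 3) and at best at 75.8 after knockdown, still listed in both libraries. The SYK region that left the strongest 50% on POU2AF1 knockdown was in 1 of 2 POU2F2 knockdown lists, at rank 99.1. In SU-DHL-4, dark zone genes had 6 members in the strongest 50%, CDK1, CDKN1A, CXCR4, E2F1, FOXO1 and RRM2, against 2.63 by chance (permutation p 0.0684, adjusted p 1), and FOXO1 and RRM2 also had regions that entered the strongest 50%.

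The regions that SU-DHL-4 lost and gained on POU2F2 knockdown were measured in OCI-Ly7 as the share of lost regions listed minus the share of gained regions listed. POU2F2 knockdown moved it by −0.780 percentage points from 2.07 ± 2.40 in controls (SD, n = 3), which is within the spread and leaves open whether the same regions respond to OCT2 in OCI-Ly7. The control of the later library series stood at 4.83 points and both POU2F2 knockdown libraries of that series at 1.11 and 1.47, and without that control, replicate 3, the difference was 0.602 points. POU2AF1 knockdown moved it by −3.47 points, to −1.40 ± 0.913 (SD, n = 4), with all 4 libraries below every control (exact p 0.0571, the smallest possible, adjusted p 0.514 over 9 tests), and by −2.09 points without control replicate 3 and −1.69 points within the series 1 to 10. The share of lost regions moved little (from 18.9% to 18.3%, exact p 0.571) and that of gained regions more (from 16.8% to 19.7%, exact p 0.229), and neither share separated the groups, so a common response to OCT2 and OCA-B stays open. The OCI-Ly7 regions measured in SU-DHL-4 moved by −4.61 points, from 16.03 ± 1.33 to 11.4 ± 0.291 (SD, n = 2 each, exact p 0.333, the smallest possible).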
